A study of Homo sapiens with 12 samples.

How the data were processed

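Single-cell RNA was measured in 12 libraries of retinal spheroids made from KhES-1, a human embryonic stem cell line carrying a Venus reporter at the RAX locus. The spheroids were of 3 types by shape, non-layered (NL), well-layered (WL) and polarized (P), each taken 5, 9, 15 and 35 days after the cells had been sorted for the reporter. Each library pooled 10 to 15 spheroids of 1 type on 1 day. Per the labels, the authors ran 10x Genomics 3' chemistry with the Single Index Kit on days 5 and 9 and the Dual Index Kit on days 15 and 35, so the kit goes with time and is shared by the 3 types on each day. The authors aligned the reads and counted UMIs with Cell Ranger 6.1.1 on the human genome GRCh38. The deposited matrices hold raw UMI counts, whole numbers per gene and cell barcode, with no normalization. The deposited feature lists give Ensembl identifiers with gene symbols, the same 36601 genes in every library, and the deposited barcode lists give the cell barcodes as text. Whether the authors filtered barcodes beyond Cell Ranger's call is not stated.

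The 12 matrices held 122317 barcodes, from 7020 to 12418 per library, and 68341462 to 106926303 UMIs per library. Barcodes with at least 1000 genes and at most 15% mitochondrial UMIs were kept, which left 117973 cells and removed 4344. Doublets were scored with Scrublet in scanpy 1.11.5. The automatic call marked 0.09% or fewer of the barcodes in 5 of the early libraries, so no doublet was removed from the values reported. As an alternative, the top scores of each library were removed at a rate of 0.8% per 1000 barcodes.

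Counts per cell were log-normalised, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 gave 28 clusters. A cluster was named for 1 of 12 classes of cells with fixed markers. It took the class with the most of its 10 leading genes, at least 2 of them, when at least 3 markers of that class were high. Otherwise it took a class with at least 5 high markers that made up at least 50% of its markers, unless another class had more markers than it among the leading genes against clusters of other classes, or led with at least 2 among the leading genes against all clusters. A marker was high at 33.3% or more of its highest cluster, in at least 10% of the cells. The markers were fixed before the data were examined. The rule was set after the high markers of each cluster had been seen and before shares were computed: a first rule, the highest share of high markers with at least 3 of them, put keratin-rich pigmented clusters under lens and surface ectoderm, and it is given as an alternative. Names stand for marker expression, so classes are called progenitor-like, ciliary margin-like and so on. Clusters 1 and 2, named progenitor-like by the share of high markers, had 1 marker of another class and none of their own among their leading genes against all clusters, and no fewer of their own than of another class against clusters of other classes. Clusters 3, 16 and 19 met the marker share of progenitors and were left unnamed because of their leading genes, so the line between these sets is thin and both are varied below.

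Cells with a UMI of a gene were counted after each cell of at least 3000 UMIs had been thinned to that depth, without shallower cells. A cell was counted as HOX-positive with at least 2 UMIs over 39 HOX genes at that depth. Where HOX-positive cells were removed, and in the tests on doublets and on RAX and SIX6, the rule was at least 3 HOX UMIs at full depth. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. Since cells of a library share spheroids, intervals of this kind are not a measure of the spread between cultures.

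There was 1 library per type and day, so no group had a replicate. Each group held replicate 1 only, so replicate numbers pair no libraries, and libraries were matched by their shared day in the gene model and in the permutations. Genes were tested on counts summed per library with edgeR 4.0.16 (R 4.3.3), quasi-likelihood F test, TMM scaling and its default filter on low counts. The model held type and day, so that the spread is what departs from type plus day, with 6 residual degrees of freedom. Contrasts were WL minus NL, P minus NL, WL minus P and day 35 minus day 5 in all cells, and the 3 type contrasts in progenitor-like cells. Fold changes over time within each index kit were read from the same model without a test, a choice made after the results were seen. The interaction of type with period, days 15 and 35 against days 5 and 9, had 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. Means over the 4 days are given as CPM (counts scaled to a common library total) after TMM scaling with the SD over libraries (n = 4), which includes the differences between days. Fold changes carry the SE of the fit.

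Class shares were compared among types by an exact permutation test over the 1296 rearrangements of type labels within days, two-sided by construction, adjusted over the 7 named classes. The smallest p it can give is 0.00463, and 0.0278 with 3 days. For 29 gene lists fixed before the data were examined, the members past the threshold were counted over all genes and adjusted over the list alone. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Fry tests whether the genes of a list move, on balance, one way, and compares them with no other genes. Within a single day no test was possible, and ratios of CPM are given with exact conditional binomial intervals (counting error only). Lists were placed among 10000 random lists matched on mean expression in 20 bins. A count of 0 was given a floor of 3 counts in that library.

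Genes were named by a rule set before the data were examined. In all cells it took the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with 1 sign on all 4 days and a mean of at least 20 CPM in the higher type. It took 5 and 5 in progenitor-like cells, 10 and 10 between days 5 and 35 with 1 sign in all 3 types, the 5 smallest p where fewer than 5 genes passed, and in each list past camera the 3 members with the smallest p. On single days it took the 3 highest and 3 lowest ratios among genes of at least 50 CPM. RAX, PAX6, SIX6, MITF, ZIC1, ATOH7, POU4F2, CRX, PTF1A and MKI67 were always given. Some genes that the rule names are not reported here. Read-through, antisense and unnamed genes were passed over. Positions came from GENCODE release 44 on GRCh38, which held 224 of the 225 genes named.

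Alternatives were RLE scaling, DESeq2 1.42.0, no filter on genes, no filter on cells, a stricter filter (2000 genes, 10% mitochondrial), removal of top doublet scores, no day in the model, each index kit alone, leaving out each library and each day, Leiden resolutions 0.5 and 2, and clustering without cell cycle genes. Alternatives chosen after seeing the data were the first naming rule, removal of cells with at least 3 HOX UMIs, other sets of progenitor clusters, progenitor clusters at the other resolutions, and clustering without 730 variable genes that differed between types. The tests were tried on simulated data with 200 changed genes. In all cells 95% of the genes changed by 1 on the log2 scale were recovered for WL minus NL with 12 false among 204 calls. In progenitor-like cells 99% were recovered with 23 false among 222 calls. Recovery was 16% for the interaction with 7 false among 106 calls. With no change put in, camera called 0 of 29 lists in all cells and 1 in progenitor-like cells, and 0 genes passed. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera at the preset correlation calls lists whose members vary together. Its counts followed the fitted gene dispersions. For WL minus NL a changed gene moved by the same amount on all 4 days, and genes of low expression were not changed. Recovery in the real libraries may therefore be lower.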

Results

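The data were single-cell UMI counts from 12 libraries of retinal spheroids grown from a human embryonic stem cell line, KhES-1, whose RAX locus carries a Venus reporter. RAX encodes an early eye-field homeobox factor, and reporter-positive cells had been sorted before culture. There was 1 library for each of 3 spheroid types (non-layered NL, well-layered WL, polarized P) on each of 4 days after sorting (5, 9, 15 and 35). After filtering, the libraries held 6919 to 11574 cells. Total UMIs per library, over all deposited barcodes, were 101072075, 68341462, 99032418 and 75060079 in NL on days 5, 9, 15 and 35, 95068415, 102349150, 74387994 and 93176228 in WL, and 106926303, 88223762, 76000626 and 81218645 in P. Median UMIs per cell ran from 5532 in NL on day 35 to 10120 in WL on day 5. With no replicate of any type on a day, tests compared types over the 4 days as if these were independent, though the labels do not say whether the days of a type came from 1 sort and culture, and SDs between the libraries of a type include the change over time.

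The first comparison asked which cells made up the 3 types, since the series title names sub-populations of retinal progenitors that drive the layered structure. Pigment epithelium-like cells, which expressed TTR, PMEL, TYRP1 and DCT, made up 2.4% ± 2.52 of cells in P, 0.08% ± 0.11 in WL (mean and SD, n = 4), and at most 0.01% of any NL library. Types differed in this class (exact permutation test, adjusted p = 0.0324, raw p = 0.00463, the smallest possible). Ciliary margin-like cells, led by ANXA1, IGFBP7, PMEL and WNT2B, made up 16.51% ± 29.24 in P, 4.5% ± 8.4 in WL and 0.91% ± 1.7 in NL (exact permutation test, adjusted p = 0.0486). On day 5 they were 60.2% of P, 17.08% of WL and 3.45% of NL. WNT2B marks the eye periphery and was a ciliary margin marker here, while PMEL builds pigment fibrils and was a pigment epithelium marker. At clustering resolution 2, all 4 genes were among the leading genes of a ciliary margin-like cluster of 1686 cells, 85.2% from P on day 5. They were also among those of a pigment epithelium-like cluster of 1531 cells, 86.6% from P on day 5. The ciliary margin-like cells of P on day 5 may thus include pigment epithelium-like cells.

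No class of named retinal neurons passed the threshold between types by this test, which does not show that the types were alike. On day 5 such cells were few, with 7 ganglion cell-like cells in NL, 9 in WL and 37 in P. Without day 5, ganglion cell-like and amacrine and horizontal cell-like cells each had raw p = 0.0556 (exact permutation test). Photoreceptor-like cells then had raw p = 0.111 (exact permutation test). With 3 days the exact permutation test gives no p under 0.0278. Photoreceptor-like cells reached 14.69% in WL, 9.83% in NL and 7.66% in P on day 35 (exact permutation test over all days, adjusted p = 0.136). Ganglion cell-like cells reached 12.29% in WL, 13.08% in NL and 9.34% in P on day 35 (exact permutation test over all days, adjusted p = 0.297), and their means over days, 5.77%, 6.06% and 2.48%, were 0.91%, 2.38% and 0.3% at clustering resolution 2. On day 15 ganglion cell-like cells were 9.78% of WL, 9.26% of NL and 0.15% of P. Photoreceptor-like cells on that day were 3.81% of WL, 2.93% of NL and 0.09% of P. Amacrine and horizontal cell-like cells on day 35 were 4.94% of WL, 6.6% of NL and 2.28% of P (exact permutation test over all days, adjusted p = 0.333). Neurogenic precursor-like cells on day 9 were 8.92% of WL, 7.27% of NL and 0.03% of P (exact permutation test over all days, adjusted p = 0.0729), but their mean over days, lowest in P at 1.38%, was highest in P at resolution 0.5 (11.49% against 6.6% of WL and 6.34% of NL) and in 3 other alternatives. At resolution 0.5 the class took in a cluster of 3553 cells led by SST, HOXB9, HOXB8 and HOXC8, 53.9% of them from P on day 15. A cluster with HOX genes among its leading genes joined the class in the other 3 as well. Progenitor-like cells on days 5, 9, 15 and 35 were 96.15%, 56.57%, 40.4% and 49.37% of NL, 82.77%, 80.28%, 63.04% and 51.3% of WL, and 27.22%, 6.31%, 3.76% and 37.59% of P (values only, since 2 clusters of that class had leading genes of another). Their means over days were 60.62% of NL, 69.35% of WL and 18.72% of P. With clusters 3, 16 and 19 added, which met the progenitor marker share but were left unnamed, the means were 80.27%, 74.67% and 26.14%. Cluster 3 took 56.7% of its 7580 cells from NL on day 15.

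Pigment epithelium-like cells were 8.65% of P and 0.38% of WL at clustering resolution 0.5, 5.93% and 0.47% at resolution 2, and 1.22% of P without day 9. Ciliary margin-like cells were 1.95% of P without day 5. Both class calls depended on the clustering and on the naming rule. Clustering without cell cycle genes gave adjusted p = 0.148 for both (exact permutation test), with ciliary margin-like cells at 22.6% of P and 20.17% of WL. Under the first naming rule, set aside after markers per cluster had been seen, clusters 6, 24 and 27 were lens and surface ectoderm-like, no pigment epithelium-like class existed, and the ciliary margin name went to other clusters, 37.57% of P and 0.08% of NL (exact permutation test, adjusted p = 0.0247).

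**Figure D1:**
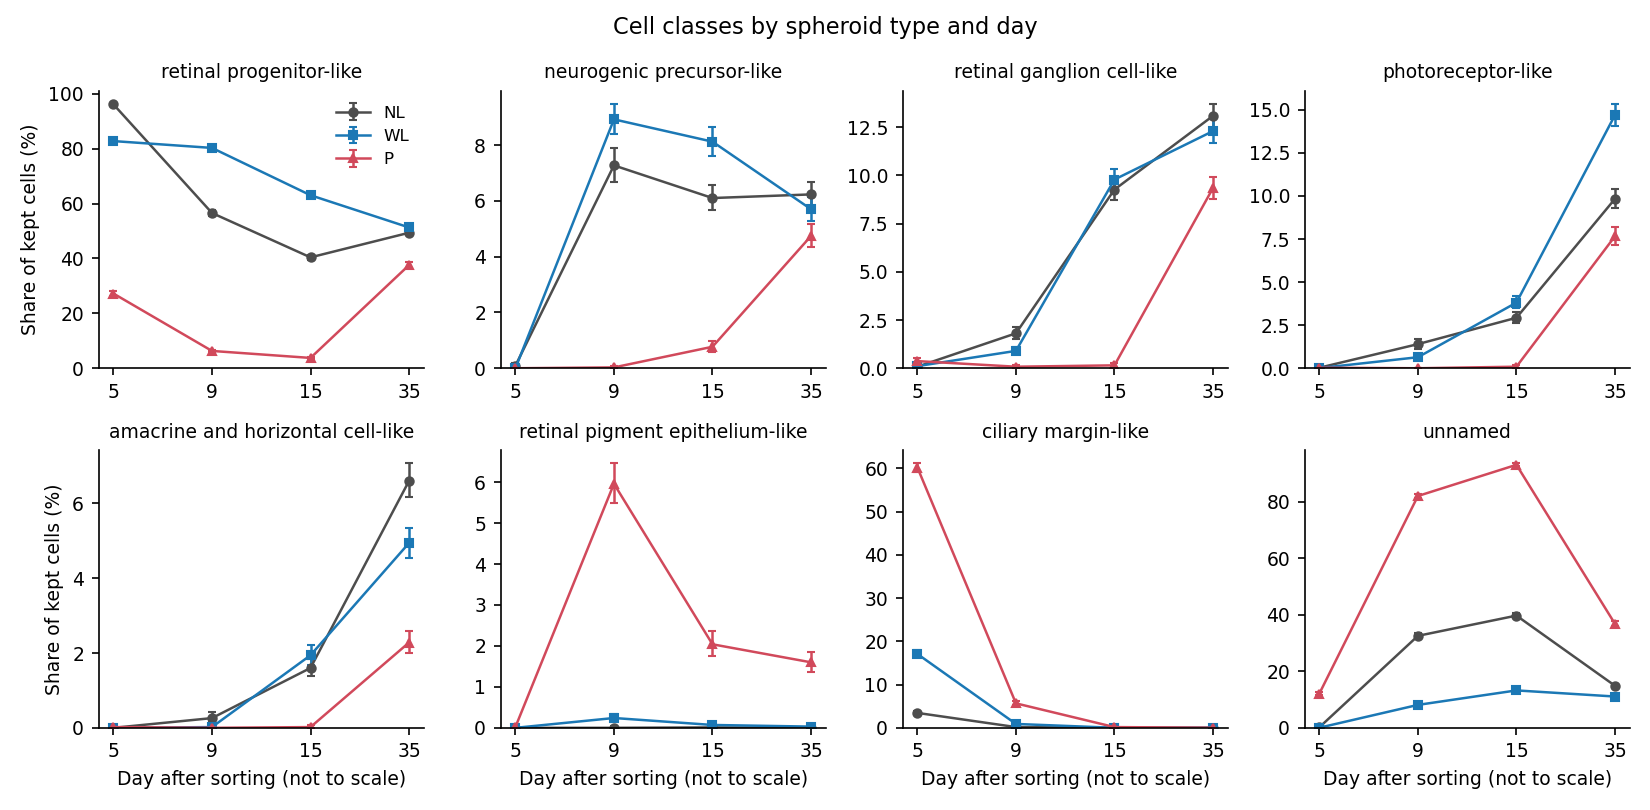
Share of cells (%) of each class by day after sorting, with exact 95% intervals for counting error and 1 library per point. On day 5 ciliary margin-like cells were 60.2% of P and 3.45% of NL.

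Marker genes counted at equal depth separated P from both other types. Cells with HOX transcripts, which specify positions behind the forebrain, made up 8.11%, 54.25%, 73.47% and 26.59% of P on days 5, 9, 15 and 35. In NL they were 0.06%, 0.03%, 0.15% and 1.49%, and in WL 0.05%, 0.2%, 0.63% and 0.65%. Within P, HOX-positive cells were 52.19%, 65.49%, 78.76% and 70.18% of unnamed cells (median depth 11801, 7811, 7925 and 8016 UMIs) and 0.11%, 1.03%, 2.51% and 1.2% of progenitor-like cells (9097, 9512, 8777 and 7134 UMIs), the class that should lack them. They were also 51.72% of ganglion cell-like cells of P on day 5 (15 of 29) and 6.49% of ciliary margin-like cells on day 9. Elsewhere in the named classes of P that were counted they were at most 3.77%. Cells with RAX were 68.02%, 73.82%, 65.12% and 58.47% of NL, 50.54%, 63.05%, 53.66% and 61.24% of WL, and 27.02%, 16.21%, 7.8% and 45.17% of P. Cells with ZIC1, a factor of the dorsal neural tube and ciliary margin, were 9.07%, 36.23%, 48.96% and 22.65% of P and 4.91%, 7.31%, 6.27% and 2.99% of NL. These shares were not tested between types.

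**Figure D2:**
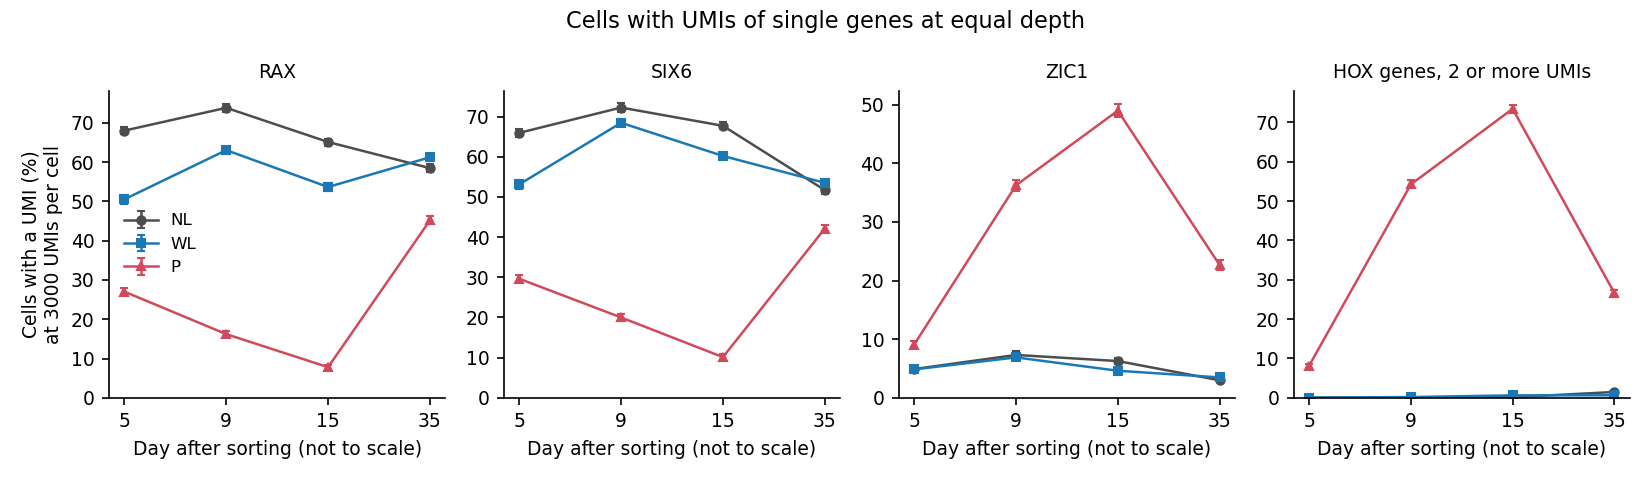
Share of cells (%) with a UMI of RAX, SIX6 or ZIC1, or with 2 or more HOX UMIs, by day after sorting, in cells thinned to 3000 UMIs, with exact 95% intervals for counting error. HOX-positive cells reached 73.47% of P on day 15 and 1.49% of NL on day 35.

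WL against NL in all cells asked what sets well-layered spheroids apart. PAX2, a factor of the optic stalk, fell by 1.68 ± 0.21 on the log2 scale in WL (SE, n = 4 per type, adjusted p = 0.0271), from 112.9 ± 70.12 CPM in NL to 34.11 ± 22.38 in WL (SD). TPM2, an actin-binding tropomyosin, rose by 1.12 ± 0.12 (adjusted p = 0.0168), from 31.52 to 63.21 CPM. FAM89A rose by 0.54 ± 0.07 (adjusted p = 0.0497) and SEMA6A, a guidance semaphorin, fell by 0.66 ± 0.09 (adjusted p = 0.0341). All 4 moved the same way on the 4 days. PAX2 (ENSG00000075891) lies on chromosome 10 from 100735396 to 100829944 and TPM2 (ENSG00000198467) on chromosome 9 from 35681992 to 35690056 of GRCh38.

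In all, 15 of 22499 genes passed between WL and NL, 4 higher and 11 lower in WL, with 2460 at an unadjusted p under 0.05. DESeq2 called 468, with 269 higher and 199 lower in WL, so the balance of higher and lower genes depended on the tool. Another split of the same libraries, days 5 and 35 against days 9 and 15, called 92 genes. With day in the model, that contrast rests on how P departs from NL and WL between those days. Of the 8 splits with 1 library of each day on each side, too few for a share under 0.05, the real one called 15 and the others 0. Beyond the named genes, AC073365.1 and TSTD1 were higher and C1QL4, CLDN4, GLYAT, HGD, PAX8, SHISA6, SLC15A3, TBC1D10C and TBX5-AS1 lower, chosen after their values were seen. Dorsal retina genes were lower in WL, with 0 of 8 members positive, a median of -0.61 and camera adjusted p = 1.15e-06 (adjusted p = 0.271 with an estimated correlation). No member passed over all genes and 3 did adjusted over the list alone. Optic stalk and ventral genes were lower as well, with a median of -0.44, 1 member past the threshold over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00105, adjusted p = 0.441 with an estimated correlation). Hypoxia and glycolysis genes were higher, 18 of 18 positive with a median of 0.40, mostly by day 9 (single-day medians of 0, 1.01, 0.26 and -0.02), and 0 past the threshold, 0 adjusted over the list alone (camera adjusted p = 1.15e-06, adjusted p = 0.476 with an estimated correlation). Immediate early and heat shock genes had a median of 0.41, 0 past and 3 adjusted over the list alone (camera adjusted p = 6.48e-06, adjusted p = 0.476 with an estimated correlation). Lens and surface ectoderm genes had a median of 0.32, 0 of 9 past the threshold and 2 adjusted over the list alone (camera adjusted p = 0.000533, adjusted p = 0.271 with an estimated correlation). Pigment epithelium genes had a median of 0.67, 0 of 12 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.0154, adjusted p = 0.476 with an estimated correlation). Endoplasmic reticulum and amino acid stress genes had a median of 0.24, 0 of 13 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.00169, adjusted p = 0.476 with an estimated correlation). Targets of p53 had a median of 0.4, 0 of 12 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.00169, adjusted p = 0.512 with an estimated correlation). Of 29 lists 11 passed camera, 0 with an estimated correlation and 0 by fry. The gene count fell to 1 without NL or WL on day 5, 9 or 15 and to 2 without WL on day 35, and rose to 21 without P on day 5, 32 without P on day 15, 24 without P on day 35 and 44 without NL on day 35, while PAX2, TPM2, SEMA6A and FAM89A stayed past the threshold in 6, 6, 5 and 2 of 13 fits with 1 library left out or RLE scaling.

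P against NL in all cells asked what sets polarized spheroids apart. HOXB9, a posterior HOX gene, averaged 209.8 ± 171.5 CPM in P and 0.1267 ± 0.2469 in NL (SD, n = 4, adjusted p = 0.000132). FEZF1, SOX21, HOXA3, HOXA4, HOXA5, HOXB6 and HOXC4 were also higher in P. PMEL rose by 3.64 ± 0.30 on the log2 scale (SE, adjusted p = 0.000175) and ZIC1 by 3.01 ± 0.43 (adjusted p = 0.00211). RAX fell by 2.16 ± 0.44 (adjusted p = 0.0101), from 423.0 to 110.4 CPM, and TBX2, a dorsal eye factor, fell by 2.91 ± 0.32 (adjusted p = 6e-04), from 119.3 to 16.62 CPM. HOXB9 (ENSG00000170689) lies on chromosome 17 from 48621156 to 48626358, TBX2 (ENSG00000121068) on chromosome 17 from 61399843 to 61409466, PMEL (ENSG00000185664) on chromosome 12 from 55954105 to 55973317 and RAX (ENSG00000134438) on chromosome 18 from 59267035 to 59274086.

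Of 22499 genes 4088 passed, 2449 higher and 1639 lower in P. The largest falls also took in SERTM2, the iron carrier TF, the Wnt antagonist DKK1, LGI4, COL13A1 and MIR503HG, from -2.79 to -3.75 on the log2 scale. Pigment epithelium genes rose, 9 of 12 past the threshold and 11 adjusted over the list alone, with a median of 3.13 (camera adjusted p = 8.65e-14, adjusted p = 0.0295 with an estimated correlation). Dorsal retina genes fell, 6 of 8 both over all genes and adjusted over the list alone, with a median of -1.84 (camera adjusted p = 6.72e-13, adjusted p = 0.0262 with an estimated correlation). Lens and surface ectoderm genes such as CDH1 and KRT8 rose, 6 of 9 by either count (adjusted p = 0.0147 with an estimated correlation), and neural crest and mesenchyme genes such as PRRX1 and COL3A1 rose in 6 of 10 and fell in 1, and adjusted over the list alone in 7 and 2 (adjusted p = 0.0295 with an estimated correlation). Retinal progenitor genes fell in 7 of 12, and in 9 adjusted over the list alone, with a median of -1.0 (camera adjusted p = 3.81e-05, adjusted p = 0.287 with an estimated correlation). Immediate early and heat shock genes rose in 5 of 12, and in 6 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 7.96e-06, adjusted p = 0.361 with an estimated correlation). Mitochondrial transcripts were higher in 10 of 10 with 4 past the threshold and 5 adjusted over the list alone (camera adjusted p = 0.00217, adjusted p = 0.486 with an estimated correlation), where P on day 5 held a median of 7.21% mitochondrial UMIs. Endoplasmic reticulum and amino acid stress genes had a median of 0.57, 8 of 13 past the threshold and 11 adjusted over the list alone (camera adjusted p = 9.53e-06, adjusted p = 0.287 with an estimated correlation). Targets of p53 had a median of 0.53, 5 of 12 past the threshold and 7 adjusted over the list alone (camera adjusted p = 0.000591, adjusted p = 0.486 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.47, 5 of 18 past the threshold and 7 adjusted over the list alone (camera adjusted p = 0.00807, adjusted p = 0.635 with an estimated correlation). Telencephalon genes had a median of 1.13, 4 of 10 past the threshold and 4 adjusted over the list alone (camera adjusted p = 0.00217, adjusted p = 0.0726 with an estimated correlation). Ciliary margin genes had a median of 0.3, 6 higher and 2 lower of 12 past the threshold and 6 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0323, adjusted p = 0.203 with an estimated correlation). The gene count was 2067 without NL on day 9, 2179 without P on day 9, 2282 without NL on day 15 and 2513 without HOX-positive cells, where 140 of the 4088 genes had the opposite sign.

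WL against P in all cells set the layered type beside the polarized one. RAX rose by 1.82 ± 0.43 on the log2 scale in WL (SE, n = 4, adjusted p = 0.0335), and TBX2 rose by 2.70 ± 0.32 (adjusted p = 0.00152). ALDH1A1, a retinoic acid enzyme of the dorsal retina, rose by 2.22 ± 0.33 (adjusted p = 0.0047), from 122.1 ± 137.8 CPM in P to 498.2 ± 377.8 in WL. DKK1, the photoreceptor phosducin gene PDC, COL13A1, FOXN4 and BHLHE22 were higher too, while SOX21, HOXB9, TTR, HOXD8, HOXB8, HOXB6 and HOXB4 were lower.

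Of 22499 genes 1910 passed between WL and P, 571 higher and 1339 lower in WL. Pigment epithelium genes were lower, 8 of 12 past the threshold and 11 adjusted over the list alone, with a median of -2.34 (camera adjusted p = 9.95e-15, adjusted p = 0.032 with an estimated correlation). Dorsal retina genes were higher in 5 of 8 by either count, also adjusted over the list alone, with a median of 0.85 (camera adjusted p = 5.92e-08, adjusted p = 0.0472 with an estimated correlation). Cell cycle genes were higher in 20 of 20, 5 past the threshold and 11 adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.413 with an estimated correlation), and lower in progenitor-like cells as given below. Photoreceptor genes had a median of 1.19 with 0 past the threshold and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.53 with an estimated correlation). Lens and surface ectoderm genes had a median of -1, 6 lower of 9 past the threshold and 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.21e-07, adjusted p = 0.0398 with an estimated correlation). Neural crest and mesenchyme genes had a median of -2.41, 6 lower of 10 past the threshold and 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.09e-07, adjusted p = 0.032 with an estimated correlation). Retinal progenitor genes had a median of 0.82, 4 of 12 past the threshold and 8 adjusted over the list alone (camera adjusted p = 3.07e-06, adjusted p = 0.212 with an estimated correlation). Endoplasmic reticulum and amino acid stress genes had a median of -0.3, 2 of 13 past the threshold and 5 adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.413 with an estimated correlation). Mitochondrial transcripts had a median of -0.32, 1 of 10 past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.413 with an estimated correlation). The gene count fell to 617 without WL and 794 without P on day 9, to 578 without WL and 1142 without P on day 15, to 959 without WL on day 35 and to 537 without HOX-positive cells, where 111 of the 1910 genes had the opposite sign. RAX and COL13A1 stayed past the threshold in 4 of 13 fits with 1 library left out or RLE scaling.

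Progenitor-like cells alone asked what differs within 1 class, whose clusters the types filled unequally. In WL against NL, CYP1B1, a gene of the dorsal retina list, fell by 1.26 ± 0.19 on the log2 scale (SE, n = 4 per type, adjusted p = 0.0095), from 1655 ± 819.1 to 730.6 ± 441.3 CPM (SD). EFNB2, a dorsal ephrin ligand, fell by 0.50 ± 0.10 (adjusted p = 0.0326) and PAX2 fell by 1.48 ± 0.21 (adjusted p = 0.00627). KRT19, an epithelial keratin, rose by 1.46 ± 0.24 (adjusted p = 0.0141). RELN, CRYGD, TPM2 and ERICH5 rose, and TF, IGSF1 and TP53I11 fell.

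Of 19718 genes 184 passed between WL and NL, 77 higher and 107 lower. Dorsal retina genes had a median of -0.52 with 0 of 8 positive, 2 past the threshold and 5 adjusted over the list alone (camera adjusted p = 5.92e-08, adjusted p = 0.15 with an estimated correlation, fry adjusted p = 0.0346). Optic stalk and ventral genes had a median of -0.37, with 2 past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.000992, adjusted p = 0.192 with an estimated correlation). Basement membrane genes had a median of -0.16, 0 past and 1 adjusted over the list alone (camera adjusted p = 0.0119, adjusted p = 0.192 with an estimated correlation, fry adjusted p = 0.0346). Endoplasmic reticulum and amino acid stress genes had a median of 0.31, 0 of 13 past the threshold and 2 adjusted over the list alone (camera adjusted p = 0.00011, adjusted p = 0.286 with an estimated correlation). Targets of p53 had a median of 0.31, 1 higher of 12 past the threshold and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000146, adjusted p = 0.192 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.37, 0 of 18 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.000167, adjusted p = 0.718 with an estimated correlation). Immediate early and heat shock genes had a median of 0.39, 0 of 12 past the threshold and 2 adjusted over the list alone (camera adjusted p = 0.000623, adjusted p = 0.42 with an estimated correlation). Lens and surface ectoderm genes had a median of 0.29, 1 of 6 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.00519, adjusted p = 0.286 with an estimated correlation). Telencephalon genes had a median of 0.26, 1 of 7 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.0198, adjusted p = 0.192 with an estimated correlation). Clusters 1 and 2 left out, 104 genes passed. The count was 108 without NL and 41 without WL on day 5, 37 without NL, 28 without WL and 345 without P on day 9, 32 without NL and 35 without WL on day 15, and 319 without NL, 101 without WL and 317 without P on day 35, while EFNB2, RELN, CRYGD and ERICH5 stayed past the threshold in 6, 6, 5 and 4 of 13 fits with 1 library left out or RLE scaling.

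In P against NL, progenitor-like cells had lower dorsal retina genes, and they sat in other clusters. On day 9 cluster 12 held 66.8% of them in P and 0.7% in NL, and clusters 1 and 5 held 46.1% and 38.7% in NL and 1.9% and 2.9% in P. On day 15 clusters 0 and 13 held 30.8% and 26.5% in P and 1.3% and 0.6% in NL. ALDH1A1 fell by 2.19 ± 0.20 on the log2 scale (SE, n = 4 per type, adjusted p = 7.29e-05), from 817.3 to 145.7 CPM. EFNB2 fell by 1.51 ± 0.10 and BAMBI, a BMP-induced pseudoreceptor, by 2.33 ± 0.15 (both adjusted p = 4.94e-06). WLS, needed to secrete Wnt proteins, rose by 6.88 ± 0.73 (adjusted p = 0.000183), from 0.2951 to 24.43 CPM. CCK, HSD17B2, SMOC1 and TENM3 rose and TF, DKK1, LGI4 and COL9A3 fell.

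Of 19718 genes 1819 passed, 1005 higher and 814 lower in P. Dorsal retina genes fell in 7 of 8 by either count, also adjusted over the list alone, with a median of -1.47 (camera adjusted p = 1.35e-27, adjusted p = 0.00533 with an estimated correlation). BMP response genes fell in 6 of 9 and rose in 1, also adjusted over the list alone, with a median of -1.0 (camera adjusted p = 6.92e-06, adjusted p = 0.206 with an estimated correlation). Immediate early and heat shock genes rose in 6 of 12, and in 7 adjusted over the list alone, with a median of 0.83 (camera adjusted p = 2.15e-11, adjusted p = 0.129 with an estimated correlation). Mitochondrial transcripts were higher in 10 of 10 with a median of 0.36, 1 past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.000285, adjusted p = 0.396 with an estimated correlation). Cell cycle genes rose in 11 of 20, and adjusted over the list alone in 12 with 1 lower (camera adjusted p = 2.11e-05, adjusted p = 0.396 with an estimated correlation). Pigment epithelium genes had a median of 2.12, 8 of 11 past the threshold and 9 adjusted over the list alone (camera adjusted p = 4.92e-11, adjusted p = 0.104 with an estimated correlation). Lens and surface ectoderm genes had a median of 0.94, 4 of 6 past the threshold and 4 adjusted over the list alone (camera adjusted p = 3.15e-07, adjusted p = 0.104 with an estimated correlation). Ciliary margin genes had a median of 0.45, 6 higher and 1 lower of 12 past the threshold and 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0249, adjusted p = 0.278 with an estimated correlation). Retinal progenitor genes had a median of -0.49, 5 lower and 2 higher of 12 past the threshold and 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.55 with an estimated correlation). Endoplasmic reticulum and amino acid stress genes had a median of 0.34, 3 of 13 past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.00204, adjusted p = 0.347 with an estimated correlation). Targets of p53 had a median of 0.26, 5 higher and 1 lower of 12 past the threshold and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00844, adjusted p = 0.294 with an estimated correlation). P held 584 and 328 such cells on days 9 and 15, and the count was 1167 without NL on day 5, 1100 without NL on day 9 and 1133 without P on day 9.

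In WL against P, progenitor-like cells had lower ALDH1A3 and VAX2, and again sat in other clusters, with 1.3% of those of WL and 66.8% of those of P in cluster 12 on day 9. ALDH1A3, a retinoic acid enzyme of the ventral retina, fell by 4.06 ± 0.56 on the log2 scale (SE, n = 4 per type, adjusted p = 0.0034), from 73.63 ± 22.48 CPM in P to 6.429 ± 5.219 in WL. VAX2, which sets ventral identity, fell by 2.27 ± 0.28 (adjusted p = 0.00179), and VAX1 passed at 1.301 CPM in P (adjusted p = 0.0363). TBX2 rose by 1.91 ± 0.19 (adjusted p = 0.000426), with BAMBI, ID4, DKK1 and TF, while WLS, SMOC1, CCK and HSD17B2 fell.

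Of 19718 genes 373 passed between WL and P, 104 higher and 269 lower. Dorsal retina genes were higher in 6 of 8, and adjusted over the list alone in 6 with 1 lower, with a median of 0.95 (camera adjusted p = 8.72e-20, adjusted p = 0.0134 with an estimated correlation). BMP response genes were higher in 5 of 9 and lower in 1, and in 6 and 1 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 5.68e-11, adjusted p = 0.0961 with an estimated correlation). Optic stalk and ventral genes were lower in 3 of 9, and adjusted over the list alone in 3 with 1 higher (camera adjusted p = 0.0208, adjusted p = 0.206 with an estimated correlation). Telencephalon genes had a median of 0.01 and a mean of -0.83, and camera called them lower with 2 of 7 past the threshold and 2 adjusted over the list alone (adjusted p = 0.047, adjusted p = 0.174 with an estimated correlation, and adjusted p = 0.0764 with RLE scaling). Mitochondrial transcripts were lower in 10 of 10 with a median of -0.37, 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 1.45e-06, adjusted p = 0.207 with an estimated correlation). Pigment epithelium genes had a median of -1.39, 5 of 11 past the threshold and 7 adjusted over the list alone (camera adjusted p = 1.42e-13, adjusted p = 0.0961 with an estimated correlation). Lens and surface ectoderm genes had a median of -0.68, 0 of 6 past the threshold and 4 adjusted over the list alone (camera adjusted p = 3.37e-05, adjusted p = 0.137 with an estimated correlation). Cell cycle genes, higher over all cells, here had a median of -0.56, 7 of 20 past the threshold and 13 adjusted over the list alone (camera adjusted p = 5.68e-11, adjusted p = 0.174 with an estimated correlation). Immediate early and heat shock genes had a median of -0.52, 4 of 12 past the threshold and 5 adjusted over the list alone (camera adjusted p = 2.05e-08, adjusted p = 0.141 with an estimated correlation). Ciliary margin genes had a median of -0.43, 4 lower and 1 higher of 12 past the threshold and 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0217, adjusted p = 0.206 with an estimated correlation). Retinal progenitor genes had a median of 0.4, 1 higher of 12 past the threshold and 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0225, adjusted p = 0.46 with an estimated correlation). Clusters 1 and 2 left out, 206 genes passed, and the count was 87 without WL and 174 without P on day 9, 164 without WL and 196 without P on day 15, and 174 without WL and 831 without P on day 35.

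**Figure D3:**
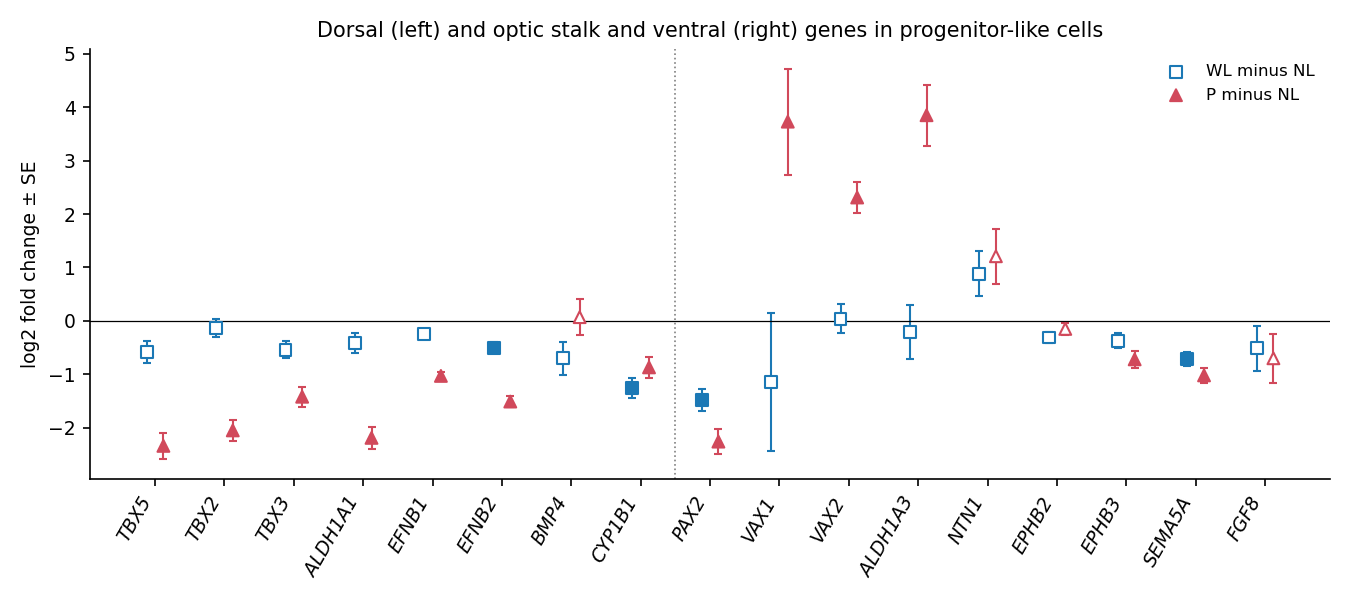
Log2 fold change (± SE) of dorsal and of optic stalk and ventral genes in progenitor-like cells, WL minus NL as squares and P minus NL as triangles, filled where adjusted p was under 0.05. EFNB2 sat at -0.50 in WL and -1.51 in P.

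Day 35 against day 5 asked how all 3 types changed over culture. PDC, a photoreceptor signalling gene, rose from 0.0194 to 64.03 CPM (mean over types, n = 3, adjusted p = 7.91e-06). ATOH7, needed to form ganglion cells, rose from 1.048 to 178.5 CPM (adjusted p = 0.00135). GJA1, a gap junction gene, fell by 4.65 ± 0.25 on the log2 scale (SE, adjusted p = 2.79e-06) and ANXA1 fell by 5.52 ± 0.36 (adjusted p = 4.64e-06). POU4F2, PDE6H, CLDN5, NEUROD4, NEUROD1, MT1G, SERTM2 and MIR7-3HG rose, and LGI1, WLS, TRPM1, CCL2, MECOM, OPTC, LYPD6B and FIBCD1 fell.

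Of 22499 genes 14438 passed, 7655 higher and 6783 lower on day 35. Cell cycle genes fell in 20 of 20 by either count, also adjusted over the list alone, with a median of -1.62 (camera adjusted p = 4.4e-15, adjusted p = 0.139 with an estimated correlation). Photoreceptor genes rose in 10 of 10, also adjusted over the list alone, with a median of 5.02 (camera adjusted p = 0.000129, adjusted p = 0.336 with an estimated correlation). Neurogenic precursor genes rose in 10 of 10, also adjusted over the list alone, with a median of 3.98 (camera adjusted p = 3.48e-07, adjusted p = 0.0672 with an estimated correlation). Basement membrane genes fell in 14 of 16 by either count, also adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.0672 with an estimated correlation). Hypoxia and glycolysis genes rose in 16 of 18, and in 17 adjusted over the list alone (camera adjusted p = 1.04e-08, adjusted p = 0.306 with an estimated correlation). The index kit changed between days 9 and 15, so a change from day 5 to day 35 includes it. Of the 14438 genes, 12333 had the same sign on the single-index days and 10577 on the dual-index days. The sign was kept on both by 8691 genes and on neither by 219. Day 9 against day 5 and day 35 against day 15 each share libraries with day 35 against day 5. Some agreement in sign is thus built in, and these counts cannot decide on the kit. Within the kits, day 9 against day 5 and day 35 against day 15, list medians on the log2 scale were 0.5 and 1.7 for photoreceptor, 2.55 and 0.49 for neurogenic precursor, -0.32 and -0.28 for cell cycle, -0.12 and -0.52 for basement membrane and 1.96 and -0.06 for hypoxia and glycolysis genes. CRX in NL went from 5.99 CPM on day 15 to 29.2 on day 35, and ATOH7 from 1.58 on day 5 to 181 on day 9.

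Whether a type difference changed from days 5 and 9 to days 15 and 35 was asked by an interaction. No gene passed edgeR for WL against NL, where 607 had an unadjusted p under 0.05 and DESeq2 called 5, nor for P against NL, where 2064 did and DESeq2 called 361. The smallest p were those of GNB3, TENM3, JPH4, F5 and UNC13C for WL (adjusted p = 1) and of HEY2, COLGALT2, RFX4, CRYAB and ID4 for P (adjusted p = 0.0871), none past the threshold. Photoreceptor genes had a median of 0.92 for WL with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 5.96e-06, adjusted p = 0.416 with an estimated correlation). Ganglion cell genes had a median of -1.51 for P, 0 past over all genes and 5 lower adjusted over the list alone (camera adjusted p = 1.75e-09, adjusted p = 0.254 with an estimated correlation). For WL their median was 0.01 and their mean -0.26, and camera called them lower (adjusted p = 0.0318, adjusted p = 0.66 with an estimated correlation). Leaving out P on day 15 gave 85 genes for P against NL, P on day 35 gave 52, P on day 9 gave 2, and WL on day 5 or 9 gave 1.

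Single days allowed no test, and ratios are given with counting intervals. On day 5 HSD17B2 was 5.63-fold higher in WL than in NL (5.3 to 5.99), with PCDH9 and KRT19 next, while COL13A1 and DKK1 were among the lowest. On day 9 PCDH9, DDIT4 and INSIG2 were highest in WL, and PAX2 and SELENOP among the lowest. On day 15 ZMAT3, PIM3 and STARD4 were highest and CYP1B1, PAX2 and MTRNR2L8 lowest, the last a gene that shares reads with mitochondrial copies. On day 35 PDE6H, a cone phosphodiesterase subunit, was 3.9-fold higher in WL (3.72 to 4.1), with RCVRN and GNB3 next, while PRPH, NSG1 and LRRC75A were lowest. Photoreceptor genes had median log2 ratios of -0.27, -0.36, 0.49 and 0.51 over the 4 days in WL over NL. Dorsal retina genes had medians of -0.86, -0.79, -0.49 and -0.38 over the 4 days in WL, at percentile 0 of the matched random lists to the decimal computed, and -0.96, -1.88, -2.51 and -1.41 in P.

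In P over NL on day 5, WLS, IGFBP5 and ATP6V1C2 were highest, and COL13A1 and ID4 among the lowest. On day 9 HOXB3, HOXB9 and HOXB6 were highest, and ATOH7, GAL and DKK1 were lowest, with ATOH7 at a ratio of 0.00384. HOXB9 and HOXB6 had 0 counts in NL. Against the floor of 3 counts HOXB9 stood at a ratio of 5320, and the lower interval bound, computed at 0 counts, was 4330. HOXB3 had 1 count in NL and no floor, so the order of these genes depends on the floor. On day 15 HOXB9, HOXB6 and HOXC4 were highest and MIR503HG, DKK1 and ATOH7 lowest. On day 35 OC90 stood at a ratio of 1270 (496 to 4660), with HOXC8 and HOXB9 next, and TF, PRPH and TBX2 were lowest.

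The remaining genes fixed for every library were read as CPM on days 5, 9, 15 and 35. ATOH7 was 1.58, 181, 247 and 199 in NL, 0.888, 145, 345 and 189 in WL, and 0.675, 0.678, 14.3 and 147 in P. MITF, a pigment cell factor, was 57.9, 43.8, 16.8 and 11.8 in P and 8.55, 8.25, 8.25 and 5.44 in NL. SIX6 was 132, 75.2, 48.1 and 196 in P and 431, 465, 412 and 239 in NL. PAX6 was 285, 316, 442 and 469 in NL, 498, 490, 582 and 493 in WL, and 500, 495, 457 and 397 in P. CRX, a photoreceptor factor, was 29.2 in NL, 46.1 in WL and 25.6 in P on day 35, POU4F2 43.7, 40.9 and 27.9, PTF1A 11.3, 5.13 and 4.7, and MKI67 107, 103 and 112.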

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

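The tests on free RNA, on RAX and SIX6 in doublets and on handling before capture, and the counts over other splits of the libraries, were chosen only after the results were seen.

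Some gene lists stood out in the interaction of type with early or late days, which tests the difference itself. Camera called 7 lists for WL against NL and 9 for P against NL, and 0 and 0 with an estimated correlation, while fry called 0 and 1. Notch pathway genes had a fry adjusted p = 0.0425 for P against NL, with 9 of 10 positive and a median of 0.61, while 0 of 10 passed over all genes, 4 were higher adjusted over the list alone, and camera gave adjusted p = 7.04e-08 (adjusted p = 0.11 with an estimated correlation).

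HOX-positive cells were 8.11%, 54.25%, 73.47% and 26.59% of P on days 5, 9, 15 and 35 and at most 1.49% of any other library. The share of HOX-positive cells among unnamed cells was at least 31.4 times that among progenitor-like cells of the same P library. This cannot decide on free RNA from other cells, since classes came from the same counts and HOX genes led several unnamed P clusters. Free RNA that reached all cells alike is argued against by RAX at equal depth. On days 5, 9, 15 and 35 it was found in 11%, 7.2%, 2.2% and 8% of HOX-positive cells and 29.8%, 26.6%, 23.4% and 58.4% of other P cells. SIX6 differed the same way. Doublets with other cells are argued against as the whole cause, since such a barcode would hold all transcripts of the other cell. Yet at full depth HOX-positive cells held RAX, and SIX6, less often. Their share was at most 0.618 times that of the other cells in each P library. Removal of the top doublet scores kept at least 83.6% of HOX-positive cells. It took too few cells to decide on days 9, 15 and 35. In each P library it kept a lower percentage of HOX-positive than of other cells, 83.6% against 92.4% on day 5. Median UMIs of HOX-positive cells were 1.644, 1.452, 0.943 and 1.069 times those of other cells on days 5, 9, 15 and 35. Doublets as part of the cause of HOX-positive cells thus stay open. Whether these cells had another origin than the sorted RAX-positive cells may be asked of RAX itself, and 11% of HOX-positive cells of P on day 5 held a RAX UMI against 29.8% of the others, which leaves it open, and the spheroid type as a biological source was not tested.

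Dorsal retina genes had a median of -0.52 in WL against NL progenitor-like cells, with 2 of 8 past the threshold (camera adjusted p = 5.92e-08, adjusted p = 0.15 with an estimated correlation). Another mix of these clusters is argued against, since 100% of 13 pairs of cluster and day had a median below 0, from -0.87 to -0.07. Pairs of a day share the same libraries, so the 13 are not independent, and another mix within single clusters was not tested. Free RNA from unnamed NL cells is argued against too, since on day 5, when they were 0.2% of NL, the median was -0.89. The spheroid type may be behind the difference, as a hypothesis found and tested on the same data.

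Immediate early and heat shock genes had a median of 0.52 in P against NL, with 5 of 12 past the threshold (camera adjusted p = 7.96e-06, adjusted p = 0.361 with an estimated correlation). The median was 0.52 under the stricter filter, equal to that without it, so the cells which that filter removes did not carry the rise. This cannot decide on damaged or shallow cells at large, since shallow cells weigh little in summed counts and damaged cells can pass both filters. HOX-positive cells are argued against by a median of 0.70 with them removed. Handling before capture stays open at 0.52, since the labels give no dissociation times, and it cannot be told apart from the type.

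Over all 35 splits of the libraries, 2 called as many genes for WL against NL in all cells, the real one with 15 and the split of days 5 and 35 against days 9 and 15 with 92. That split puts NL and WL of a day under 1 label. With day in the model, its contrast rests on how P departs from NL and WL between those days. It therefore cannot decide on chance for WL against NL, which was not excluded. For P against NL (1 of 35, real 4088, highest other 2) and WL against P (1 of 35, 1910 and 12), and in progenitor-like cells for WL against NL (1 of 35, 184 and 26), P against NL (1 of 35, 1819 and 1) and WL against P (1 of 35, 373 and 139), the share was under 0.05, but most of these splits mix days as the real one does not. The 8 splits with 1 library of each day on each side are too few for such a share (1 of 8 each, highest other 0, 0 and 1 for WL against NL, P against NL and WL against P in all cells, and 0, 1 and 0 in progenitor-like cells). For day 35 against day 5 the 10 splits are too few as well (1 of 10, 14438 and 0).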

How the results depend on the processing

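The first naming rule, removal of HOX-positive cells, the other sets of progenitor clusters, the other resolutions for progenitor-like cells and clustering without genes that differ between types were chosen only after the results were seen. The cause was not tested for any change below, beyond fewer samples where libraries or days were left out. In all cells, WL against NL gave 31 genes without a gene filter (15 higher and 16 lower in WL) and 468 by DESeq2 (269 higher and 199 lower), and WL against P gave 3041 by DESeq2. Without a day in the model WL against NL, P against NL and WL against P gave 1, 529 and 232. Over days left out they ran from 1 to 19 (2, 2 and 1 without days 5, 9 and 15), from 1175 to 3708 (1175 and 1828 without days 9 and 15) and from 326 to 1714 (326 and 524). Single-index days gave 2124 and 684 for P against NL and WL against P, dual-index days 0, 420 and 321. Without HOX-positive cells P against NL gave 2513 and WL against P 537, and 140 and 111 of the genes past the threshold with those cells had the opposite sign. Over libraries left out the counts ran from 1 to 44, from 2067 to 4531 and from 578 to 2717, for day 35 against day 5 from 12208 to 15037, and for the interactions from 0 to 0 and from 0 to 85. For the interactions DESeq2 gave 5 and 361, and no gene filter 52 for P.

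In progenitor-like cells, WL against NL gave 648 without a gene filter, 435 by DESeq2, 5 with no day, 80 and 74 on single- and dual-index days, and 72, 57 and 23 without days 5, 9 and 15 (23 to 247). It gave 104 with clusters 1 and 2 left out, 42 with clusters by marker share added, 381 at resolution 0.5 and 88 without genes that differ between types. P against NL gave 36 with no day, 774 on dual-index days and 1054, 795 and 936 without days 5, 9 and 15 (795 to 1829). WL against P gave 938 without a gene filter, 771 by DESeq2, 1 with no day, 241 on single-index days, 92, 89 and 576 without days 9, 15 and 35 (89 to 576), 206 with clusters left out, 193 with clusters added and 591 without genes that differ between types. Over libraries left out the counts ran from 28 to 345, from 1100 to 2142 and from 87 to 831.

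Class shares turned for progenitor-like cells, highest in NL, at resolution 0.5 (exact permutation test, adjusted p = 0.0278), with clusters by marker share added (adjusted p = 0.0162) and under the first naming rule (adjusted p = 0.0185). Without cell cycle genes they were highest in NL too, 31.51% against 27.58% in WL and 0.44% in P (adjusted p = 0.17). Neurogenic precursor-like cells, lowest in P, were highest in P at resolution 0.5 (11.49%), without cell cycle genes (9.39%), without genes that differ between types (11.94%) and under the first naming rule (9.44%), with adjusted p from 0.188 to 0.611, and ganglion cell-like cells were 0.91% of WL at resolution 2 (5.77% at resolution 1). In each alternative with P highest, the neurogenic precursor-like class took in a cluster with HOX genes among its leading genes. Pigment epithelium-like and ciliary margin-like cells were past the threshold no longer without cell cycle genes (adjusted p = 0.148 for both). Over days left out their adjusted p ran from 0.0778 to 0.194 and from 0.0972 to 0.259 with P highest each time, which says nothing about stability, since 3 days give no p under 0.0278. The first rule gave no pigment epithelium-like class and resolution 0.5 no amacrine and horizontal cell-like class. Lists past camera fell with an estimated correlation to 0, 4, 4, 0, 0 and 0 in all cells and to 0, 1 and 1 in progenitor-like cells, and with RLE scaling only from 18 to 17 for WL against P in progenitor-like cells, by telencephalon genes. Of 364 named gene results 0 reversed with a library left out or RLE scaling. With a library left out 329 of their values were weaker and 68 stronger, and over both kinds FAM89A was past the threshold no longer in 11 of 13 fits, ERICH5 in 9, CRYGD in 8 and EFNB2 in progenitor-like cells of WL against NL in 7. No filter on cells was not run for progenitor-like cells, and cells of under 3000 UMIs limit what the shares of marker genes can show.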

Other observations

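The values below were read after the clusters had been seen, and no test was run on them. Cluster 3, unnamed, held 7580 cells, 56.7% of them from NL on day 15, and had SLC7A10, CP, DKK1 and PAX2 among its leading genes. Cluster 10 took 95.4% of its cells from P on day 15 and was led by WNT7B, EDNRB and HOXB genes. Cluster 16, with CCK, EFNA1 and BMP2, took 90.8% from P on day 9, and cluster 26, with PTN, CA2 and EDNRB, took 97% from P on day 35. Cluster 14, led by SST with HOXC8 and HOXB9, took 52% from P on day 15. Cluster 19 held 86.5% top doublet scores.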
